A study of Mus musculus with 30 samples.

How the data were processed

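RNA from sorted mouse blood and bone marrow cells, and from cultured cells, was measured by poly-A selected RNA sequencing in 30 libraries. The libraries were non-stranded TruSeq v2 preparations read as 51 bp paired ends on a HiSeq instrument. The processing notes name bcl2fastq 2.17, FastQC 0.11.5, Trimmomatic 0.36, TopHat2 2.1.0 and Cufflinks 2.2.1 and the mm10 build, without giving the order or the settings of each step. The deposited values are FPKM (fragments scaled by transcript length and mapped fragments), with 1 value for each of 23060 gene symbols in each library. Any normalisation between libraries is not stated. Of these symbols, 3744 were at 0 in every library, and no immunoglobulin or T cell receptor segment was listed.

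Libraries were grouped by their titles into 11 groups: 13 control libraries, 13 libraries titled rEC and annotated as derived, read as blood and marrow cells descended from converted endothelium, and 3 libraries of cultured converted cells. The remaining library, titled as B220+ cells of clone 47G1 but annotated as wild type, has no clear group and was left out of every comparison. The replicates are separate libraries. The labels do not say that each came from another animal. The p-values thus measure the spread between libraries within groups, pooled over all groups, which need not be that between animals. Replicate numbers carry no stated pairing and were not used as pairs.

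Depth was not used in absolute terms, since FPKM carry no counts. Relative depth was estimated as the most frequent ratio between libraries among genes under 0.5 FPKM in both, where the value of a single fragment sets the ratio. The reference was B cell control replicate 2. Relative depth ranged from 0.588 to 1.133 of the reference library. No counting interval can be given for FPKM, and low values have the least precision.

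Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend and moderated variances, in a single model with 1 mean per group over the 29 grouped libraries, leaving 18 residual degrees of freedom. Genes at 1 FPKM or more in at least 2 libraries were tested, 14083 in all. Within each comparison p-values were adjusted by Benjamini-Hochberg and called at 0.05. The comparisons were rEC against control in each of 5 cell types, the cultured cells against both kinds of LKS-SLAM cell, the mean of the 5 origin differences, and an F test of the 4 independent differences between them. All limma tests were two-sided except the F test, which has no direction. In every library group the spread was pooled over all groups, so groups of 2 libraries were assumed to vary like the others. The groups did not vary alike. The mean distance within a group, as 1 minus Pearson's r, was 0.1412 in rEC LKS-SLAM cells. It was 0.0079 to 0.0514 in the other sorted groups, so p-values for rEC LKS-SLAM cells may be too small.

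Gene lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. A total of 39 lists were fixed, and 626 of their 639 memberships were in the table. Of 312 tests of a list in a comparison, 112 passed with the preset correlation and 15 with estimated ones. The counts of members that passed or the medians are given beside the lists that are described. Some genes stand in more than 1 list.

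The distance between origins was the mean of 1 minus Pearson's r between libraries of different origin minus the mean within origin, averaged over the 5 cell types. It was tested by an exact one-sided permutation of origins within cell type over all 288000 assignments. Lineage differences were compared across genes without a test. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 for the plots.

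The groups, the comparisons, the lists, the other settings to be tried and the rule for naming genes were set before the data were examined. Per comparison the rule names up to 10 genes with the largest rise and 10 with the largest fall among genes that passed, with no overlap between the groups and a mean of at least 5 FPKM in the higher group. Unnamed gene models are left out by the rule and counted. Where no gene passes, the 3 with the smallest p are given. Up to 4 members per list are described, and the FGRS factors and the sorting markers are named besides, with fewer of them in the comparisons of cultured cells. The marker Ly6g has no entry in the table. A few genes that the rule names are not reported. For the mean of 5 origin differences the condition on overlap was replaced by the same sign in all 5 cell types, which was decided after the data were seen. Positions are GENCODE coordinates on mm10, matched by symbol for 21993 symbols.

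The model was tested on simulated data made by adding known changes to 200 genes. Changes of 2 on the log2 scale were recovered for 82 to 95% of genes in the pairwise comparisons and changes of 1 for 37 to 64%, with 2 to 8 false calls. For the mean difference these were 99 and 91%, with 5 false calls, and for the F test 83 and 13%, with 1. A planted list of 20 genes passed camera, and 0 of 39 unchanged lists did. The distance test passed in 20 of 20 runs with a planted effect and in 0 of 20 without. The simulated noise was independent between genes, with the same spread in every library for a gene. These runs thus do not test correlated genes or libraries that stand apart, and false calls in the real data can be more.

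The alternatives were another pseudocount (0.1), no filter or a filter of 5 FPKM, quantile normalisation, array quality weights, a model of the compared groups alone, a minimum log2 difference of 1, replicate numbers as a block, and leaving out each library in turn. Others were chosen after seeing the data: leaving out both libraries that stood apart from their groups (B cell rEC replicate 1 and LKS-SLAM rEC replicate 2), the level of the ribosomal transcript Rn45s as a covariate, and both together. Human reads from the co-culture partner of the cultured cells, sequence reads and splice forms were not analysed here.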

Results

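Gene expression was measured in 5 sorted cell types and in a culture. LKS-SLAM cells, the bone marrow fraction enriched for long-term haematopoietic stem cells, gave 3 control and 3 rEC libraries. Blood gave Gr1+ Cd11b+ myeloid cells (2 control, 2 rEC), B220+ B cells (3 and 3), CD4 T cells (2 and 2) and CD8 T cells (3 and 3). Here rEC stands for the libraries annotated as derived, read as blood and marrow cells descended from converted adult endothelial cells, and FGRS for the transcription factors Fosb, Gfi1, Runx1 and Spi1. LKS-SLAM and B cell rEC replicate 2 are titled as clone 47G1, primary. LKS-SLAM and B cell rEC replicate 3, CD4 rEC replicate 2 and CD8 rEC replicates 2 and 3 are titled as secondary. The other rEC titles name no recipient, so the replicates of these rEC groups may differ by transplant. The remaining 3 libraries were adherent FGRS cells sorted as KLS (Kit+, lineage-negative, Sca1+) on day 28 of co-culture with human umbilical vein endothelial cells. Between 10165 and 12550 genes reached 1 FPKM in a library, and summed FPKM ranged from 510115 to 727885. In the CD4 control replicate 1 library the small RNA model Gm25500 took 24.0% of the summed FPKM. Relative depth ranged from 0.588 to 1.133.

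Among the genes of the surface markers used for sorting, Kit, Cd4, Cd8a and Itgam were highest in the cells sorted with them, while Ly6a was higher in control B cells (212 ± 85.7 FPKM) and CD4 cells (226 ± 26.4) than in control LKS-SLAM cells (87.8 ± 21.5). Kit, the stem cell factor receptor, stood at 124.7 ± 8.57 FPKM (SD, n = 3) in control LKS-SLAM cells and 109 ± 45.8 (n = 3) in rEC LKS-SLAM cells, against 0.0541 ± 0.0310 (n = 3) in control B cells. Cd4 stood at 358 ± 8.44 FPKM (n = 2) in control and 276 ± 47.7 (n = 2) in rEC CD4 cells, and Cd8a at 377 ± 16.6 and 406 ± 17.3 (n = 3 each) in CD8 cells. Itgam, which encodes CD11b, stood at 409 ± 5.64 FPKM in control and 397 ± 21.7 in rEC myeloid cells (n = 2 each). In B cell rEC replicate 1, however, Cd3e, a T cell receptor subunit, stood at 198 FPKM, Cd8a at 184 and Cd4 at 52.8.

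**Figure D1:**
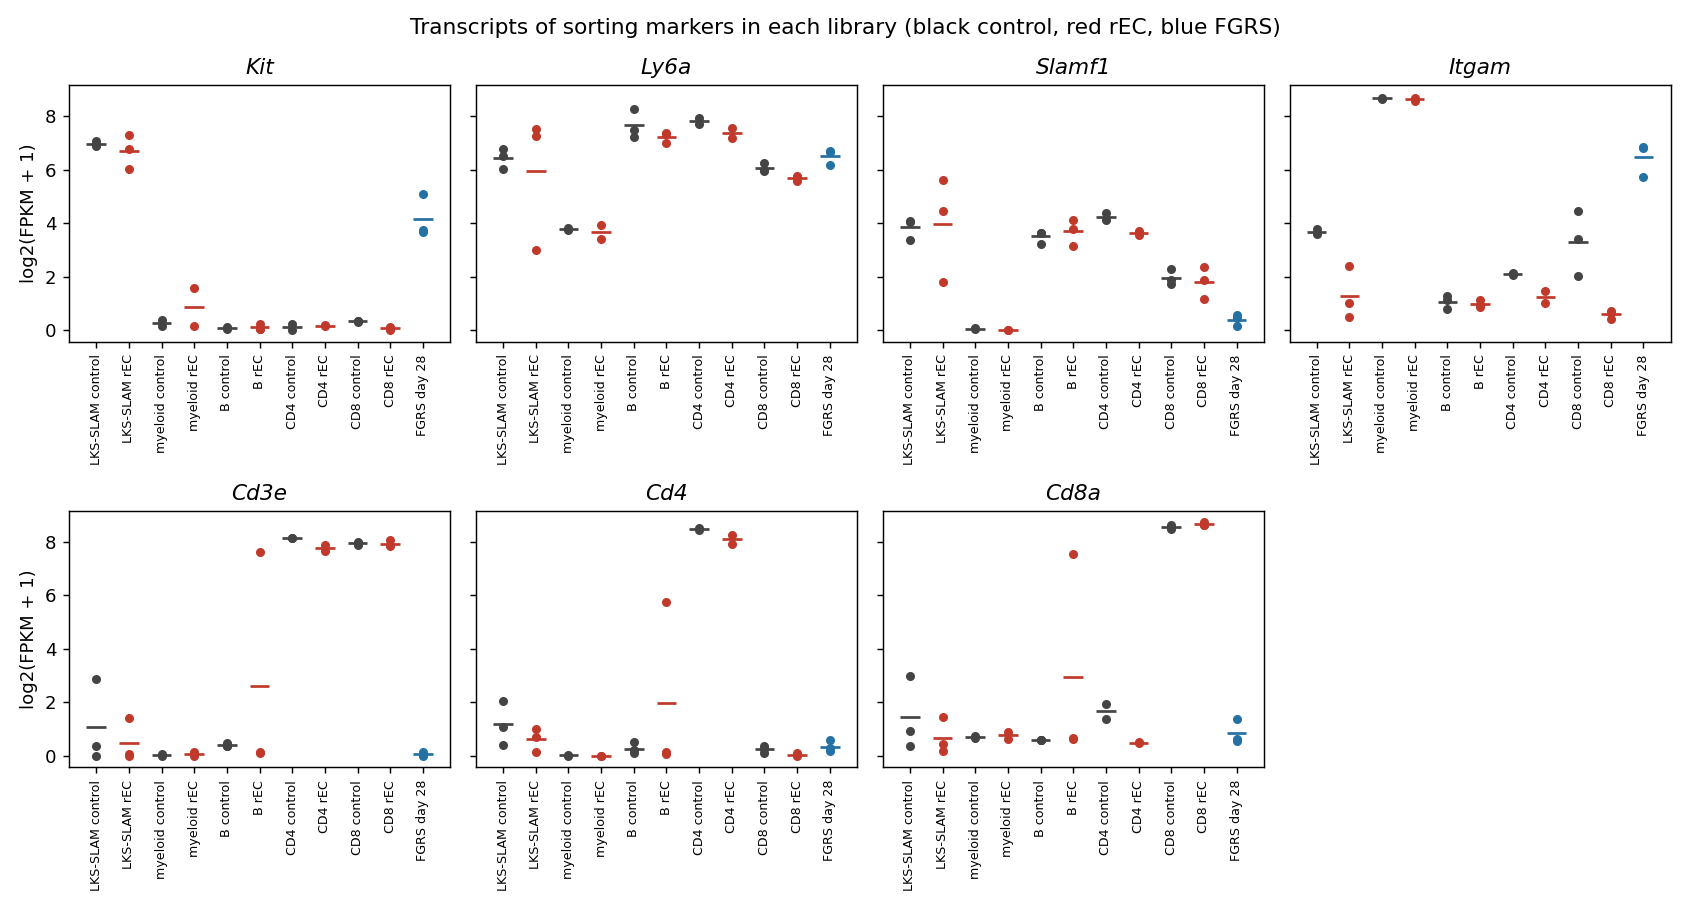
Expression of 7 sorting marker genes as log2(FPKM + 1) in each of 29 libraries, by group; points are libraries, bars are group means, control in black, rEC in red and FGRS culture in blue. Cd4 and Cd8a are high in their T cell groups and Kit in the LKS-SLAM groups, with 1 rEC B cell library carrying Cd3e, Cd4 and Cd8a as well.

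The first comparison asks how far marrow stem cells descended from converted endothelium resemble native ones. In rEC LKS-SLAM cells, transcripts of granulocyte proteins were lower than in controls. Retnlg, a resistin-like secreted protein of neutrophils (chromosome 16, 48872621 to 48874496), fell by 6.48 ± 0.47 on the log2 scale (limma, SE, adjusted p = 4.5e-08), from 143 ± 46.7 to 0.737 ± 1.07 FPKM (n = 3 each). The primary granule enzymes Mpo (myeloperoxidase), Elane (neutrophil elastase) and Ctsg (cathepsin G) fell by 5.3, 4.7 and 4.58. The basophil protease Mcpt8 fell by 5.28, the siderophore-binding protein Lcn2 by 4.38 and the haemoglobin scavenger Hp by 3.92. Jchain, the joining chain of secreted antibodies, fell by 5.07 ± 1.02 (adjusted p = 0.00991). S100a9 and S100a8, a calcium-binding pair abundant in neutrophils, fell by 5.46 and 5.33, and these calls ended without control replicate 1, control replicate 2 or rEC replicate 3. Both calls also ended with a pseudocount of 0.1, and that of S100a8 with array quality weights.

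Of 14083 genes tested, 186 passed in limma, 10 higher and 176 lower in rEC, and 153 of them by at least 1 on the log2 scale. In a model of the 6 LKS-SLAM libraries alone 0 genes passed, so each call of this comparison rests on the spread pooled over all groups (limma, 1325 at an unadjusted p under 0.05 in the pooled model). Over all genes 6.44% showed no overlap between the groups, where chance gives 10% for 3 against 3. The unnamed gene models among the 186 numbered 7. After quantile normalisation the balance was 88 higher and 114 lower. Among the 4 named rises, Mex3d, an RNA-binding protein, rose by 0.88 ± 0.18 (adjusted p = 0.0127), from 3.64 ± 0.191 to 7.57 ± 1.16 FPKM. The metallothionein Mt2 rose by 2.2 ± 0.52 (adjusted p = 0.0307), a call that ended without control replicate 1 or 3 or rEC replicate 2 or 3. The Mt2 call also ended with a pseudocount of 0.1 and with array quality weights. Arhgef25 and Aggf1 rose by 0.66 and 0.52. The Arhgef25 call ended without control replicate 3 or rEC replicate 3, and that of Aggf1 without any of the 3 controls. The Arhgef25 call also ended with a pseudocount of 0.1 and with a filter of 5 FPKM.

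Among the fixed lists, 12 of 19 neutrophil genes fell (18 adjusted over the list alone, median −3.73, camera adjusted p = 1.67e-34, and adjusted p = 0.00158 with an estimated correlation). Of 10 plasma and germinal-centre B cell genes 3 fell (5 adjusted over the list alone, adjusted p = 6.61e-05, and adjusted p = 0.00987 with an estimated correlation), among them Mzb1, a chaperone of antibody assembly, by 2.77 and Irf4, a plasma cell transcription factor, by 2.0. Of 17 genes of the unfolded protein and integrated stress response 2 fell (6 adjusted over the list alone, adjusted p = 5.89e-05, and adjusted p = 0.00987 with an estimated correlation): Herpud1 by 0.98 and Atf4 by 0.75. Of 11 stromal genes 3 fell (7 adjusted over the list alone, adjusted p = 2.34e-07, and adjusted p = 0.0414 with an estimated correlation), with the marrow niche chemokine Cxcl12 lower by a log2 difference of −3.09. These list members rest on single controls or rEC replicate 3: the Cxcl12 call ended without control replicate 1 or 2, Atf4 without control replicate 1 or 2 or rEC replicate 3, Irf4 without control replicate 1 or 3 or rEC replicate 3, and Mzb1 without rEC replicate 3.

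Further lists passed with the preset correlation alone. Of 9 eosinophil genes 3 fell (8 adjusted over the list alone, adjusted p = 2.36e-08, and adjusted p = 0.158 with an estimated correlation). Of 11 mast cell and basophil genes 4 fell (6 adjusted over the list alone, adjusted p = 5.89e-05, and adjusted p = 0.193 with an estimated correlation), among them Hdc, the histamine-forming enzyme, by 2.79. Of 20 immediate early genes 2 fell (11 adjusted over the list alone, adjusted p = 5.03e-13, and adjusted p = 0.248 with an estimated correlation), Egr3 by 2.45 and Egr2 by 1.55; both calls ended without control replicate 1 or control replicate 2, and that of Egr3 also without rEC replicate 2. The eosinophil granule protein Prg2 stood at 1863 and 3398 FPKM in control replicates 1 and 2 and at 31.5 in control replicate 3. The mean log2 of the eosinophil list was 5.96 and 6.67 in control replicates 1 and 2 and 1.17 in control replicate 3. In rEC replicates 1, 2 and 3 it was 0.45, 3.71 and 0.23. The mast cell and basophil list stood at 4.65, 4.57 and 2.25 in control replicates 1, 2 and 3. It stood at 1.96, 3.12 and 1.55 in the rEC replicates. In both lists rEC replicate 2 lay above control replicate 3, which was nearer to rEC replicates 1 and 3 than to the other controls. Whether mature cells were among the sorted control cells was not tested, so these falls need not be changes within stem cells.

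No gene of the 26-member stem cell list passed (median −0.47, adjusted p = 0.138, or 0.0342 after quantile normalisation). Ly6a, which encodes Sca1, stood at 115 ± 94.7 FPKM in rEC and 87.8 ± 21.5 in control cells, and Slamf1, which encodes CD150, at 23.7 ± 22.7 and 13.7 ± 3.77. The markers Cd48 and Ptprc did not pass, with log2 differences of −1.61 and −0.67, while Itgam fell by 2.39 ± 0.44 (adjusted p = 0.00504). The factors Fosb, Gfi1, Runx1 and Spi1 did not pass; Fosb stood at 213 ± 169 FPKM in rEC and 624 ± 54.0 in control cells. LKS-SLAM rEC replicate 2 (titled as clone 47G1, primary) stood apart from its group: the mean log2 of the stem cell list was 3.09 there and 5.09 to 6.17 in the other 5 LKS-SLAM libraries. Its Ly6a stood at 6.99 FPKM, its Slamf1 at 2.46 and its erythroid factor Klf1 at 201. The negative median of the stem cell list rests on this library: without it and B cell rEC replicate 1 the median was 0.56. As the library was set apart for this list, no rise is read from that value.

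Without that library and B cell rEC replicate 1, a choice made after seeing the data, 1554 genes passed between the LKS-SLAM groups, 597 higher and 957 lower, and 183 of the 186 above were among them. The library was set apart for its low stem cell list and also has all 36 cell cycle genes at their highest of the 6 libraries, so no change in these lists is read from the fit without it. The lists that had passed with estimated correlations no longer did (neutrophil adjusted p = 0.0738, plasma and germinal-centre B cell 0.111, unfolded protein and integrated stress response 0.111, stromal 0.219), and their medians stayed negative. With every library the cell cycle median was −0.45 and 0 of 36 genes passed in limma, also adjusted over the list alone (camera adjusted p = 0.00519, and adjusted p = 0.768 with an estimated correlation). Leaving out a single library gave 1256 genes without rEC replicate 2, 419 without rEC replicate 1, 385 without rEC replicate 3, 329 without control replicate 3, 117 without control replicate 2 and 101 without control replicate 1.

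**Figure D2:**
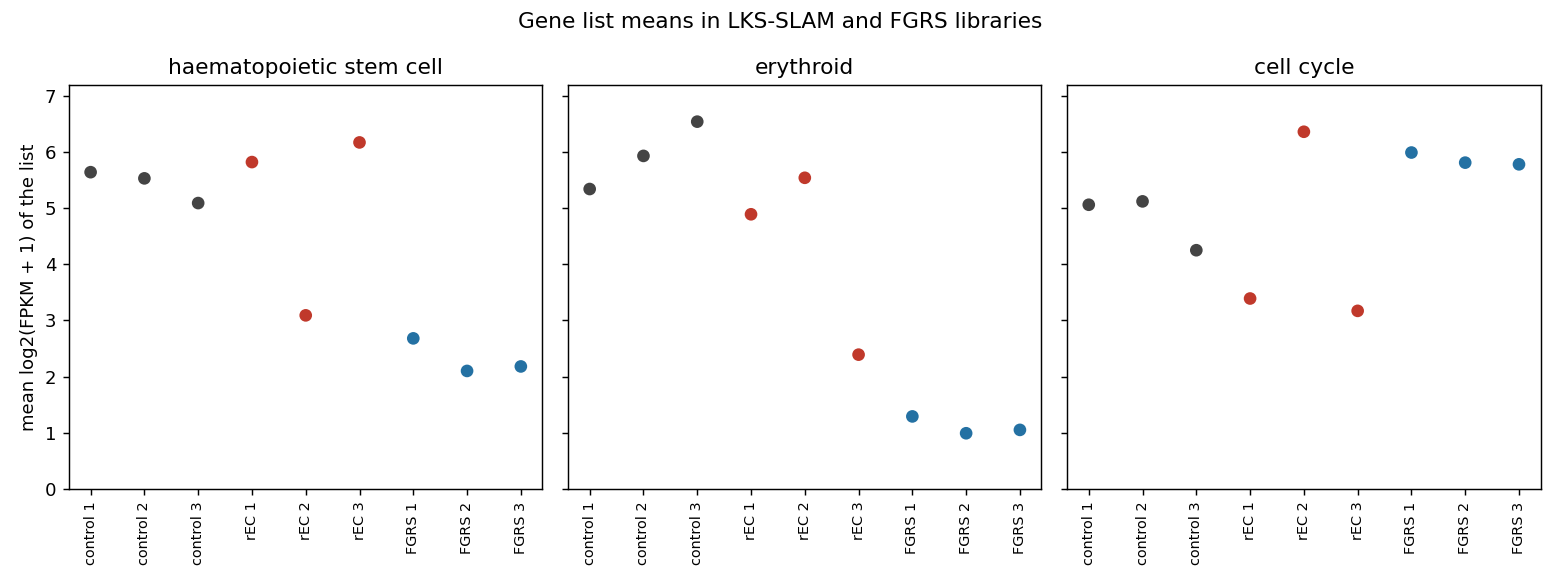
Mean log2(FPKM + 1) of the stem cell, erythroid and cell cycle lists in each of 9 libraries (3 control LKS-SLAM, 3 rEC LKS-SLAM, 3 FGRS culture); points are libraries. The stem cell list stands at 3.09 in LKS-SLAM rEC replicate 2 and between 5.09 and 6.17 in the other LKS-SLAM libraries.

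The second comparison asks how the cultured converted cells differ from native stem cells. Several of the largest rises in FGRS cells were in genes known from macrophages. Spp1, which encodes the secreted glycoprotein osteopontin (chromosome 5, 104435118 to 104441050), rose by 6.58 ± 0.71 on the log2 scale (limma adjusted p = 4.43e-07), to 2217 ± 1586 FPKM from 24.2 ± 22.1 (n = 3 each). The galectin gene Lgals3 rose by 5.17 to 595 ± 383 FPKM from 12.7, the arginase Arg1 by 5.3 to 113 ± 103 from 0.614, and Gpnmb, a glycoprotein of macrophages, by 5.83 to 99.04 from 0.201. The chemokine Ccl7 and the macrophage elastase Mmp12 stood at 74.0 ± 66.6 and 52.5 ± 35.4 FPKM and were listed at 0 in all 3 controls. Slc16a3, a lactate exporter, rose by 4.95 ± 0.31, and Cox6a2, Ms4a6d and the hormone gene Stc2 by 5.54, 5.45 and 4.93.

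Among the largest falls was Sult1a1, a sulfotransferase of the stem cell list, which fell by 6.49 ± 0.97 (limma adjusted p = 2.01e-05) to 0.477 ± 0.334 from 156 ± 98.0 FPKM. Retnlg fell by 6.35, the carbonic anhydrase Car1 by 6.35 and Egr1, an immediate early factor, by 6.2 ± 0.84 to 19.1 from 1302 ± 222 FPKM. The haemoglobin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-bs and the eosinophil gene Ear1 were listed at 0 in all 3 FGRS libraries, and reads may be shared between such close gene copies. The Hbb-bs call ended without control replicate 3 or FGRS replicate 2 or 3.

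Of the 4 factors, Fosb fell by 5.9 ± 0.83 (adjusted p = 1.04e-05) to 9.59 ± 2.06 from 624 ± 54.0 FPKM. Spi1 rose by 1.61 ± 0.48 (adjusted p = 0.00861) to 241 ± 67.4 from 76.4 ± 11.3. Runx1 fell by 0.96 ± 0.3 (adjusted p = 0.012), a call that ended without control replicate 3 or FGRS replicate 2, and Gfi1 did not pass (−0.29; adjusted p = 0.633). Values of a factor do not separate the transduced from the native transcript. Kit fell by 2.81 ± 0.33 to 18.9 ± 12.1 FPKM and Slamf1 by 3.45, Itgam rose by 2.79, and Ly6a did not pass (0.07; 91.7 ± 17.2 against 87.8 ± 21.5 FPKM). Cd48 rose by 1.8 (adjusted p = 0.0283), a call kept only without control replicate 3 among the 6 leave-outs.

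Of the lists, 16 of 18 cholesterol synthesis genes rose (16 adjusted over the list alone, median 2.03, camera adjusted p = 3.32e-16, and adjusted p = 0.0023 with an estimated correlation), among them Fdps by 3.7 and Msmo1 by 3.33. Of 21 glycolysis and hypoxia genes 15 rose and 1 fell (the same counts adjusted over the list alone, median 2.1, adjusted p = 1.54e-11, and adjusted p = 0.0138 with an estimated correlation), with Eno1 at 830 against 89.4 FPKM and Pgk1 at 1238 against 160. Of 17 unfolded protein and integrated stress response genes 10 rose (10 rose and 1 fell adjusted over the list alone, median 1.36, adjusted p = 2e-06, and adjusted p = 0.00397 with an estimated correlation), among them the cystine transporter Slc7a11 by 3.88 ± 0.14 and the asparagine synthetase Asns by 2.76. Without both libraries that stood apart in other groups, the adjusted p with an estimated correlation was 0.0191 for cholesterol synthesis and 0.0544 for each of the other 2 lists.

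Other lists passed with the preset correlation alone. Of 26 stem cell genes 24 fell (24 adjusted over the list alone, median −3.15, adjusted p = 9.88e-10, and adjusted p = 0.586 with an estimated correlation), with Pdzk1ip1 lower by −4.49 and Vwf by −4.15. Of 19 monocyte and macrophage genes 16 rose (17 adjusted over the list alone, median 3.36, adjusted p = 1.35e-09, and adjusted p = 0.259 with an estimated correlation), among them the complement gene C1qb by 4.92, the lysosomal protease Lgmn by 4.65 and the antibody receptor Fcgr1 by 4.16. Of 30 interferon response genes 24 fell and 1 rose (the same counts adjusted over the list alone, median −1.7, adjusted p = 1.59e-05, and adjusted p = 0.639 with an estimated correlation), of 16 Hox genes 14 fell (14; median −2.26, adjusted p = 0.000211, and adjusted p = 0.716 with an estimated correlation), and of 22 endothelial genes 14 fell and 1 rose (the same counts adjusted over the list alone, median −1.22, adjusted p = 0.00306, and adjusted p = 0.639 with an estimated correlation). The endothelial junction gene Cldn5 and the receptor Tie1 fell by 5.2 and 4.25, while Stab1, a scavenger receptor also found on macrophages, rose by 3.84. Of 20 immediate early genes 18 fell (18 adjusted over the list alone, median −3.84, adjusted p = 1.8e-05, and adjusted p = 0.639 with an estimated correlation). Of 36 cell cycle genes 12 rose (1 adjusted over the list alone, median 1.07, adjusted p = 7.19e-06, and adjusted p = 0.803 with an estimated correlation).

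In all, 6870 genes passed (48.8% of those tested), 2411 higher and 4459 lower in FGRS cells, and 3749 differed by at least 1 on the log2 scale. Over all genes 58.6% showed no overlap between the groups, where chance gives 10%. The median over all genes was −0.194, or 0.032 after quantile normalisation, which gave 2944 higher and 2864 lower; changes near that shift have no firm direction. The FGRS gate had no SLAM markers, and the cells came from culture while the controls were freshly isolated, so gate, culture and origin differ together.

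**Figure D3:**
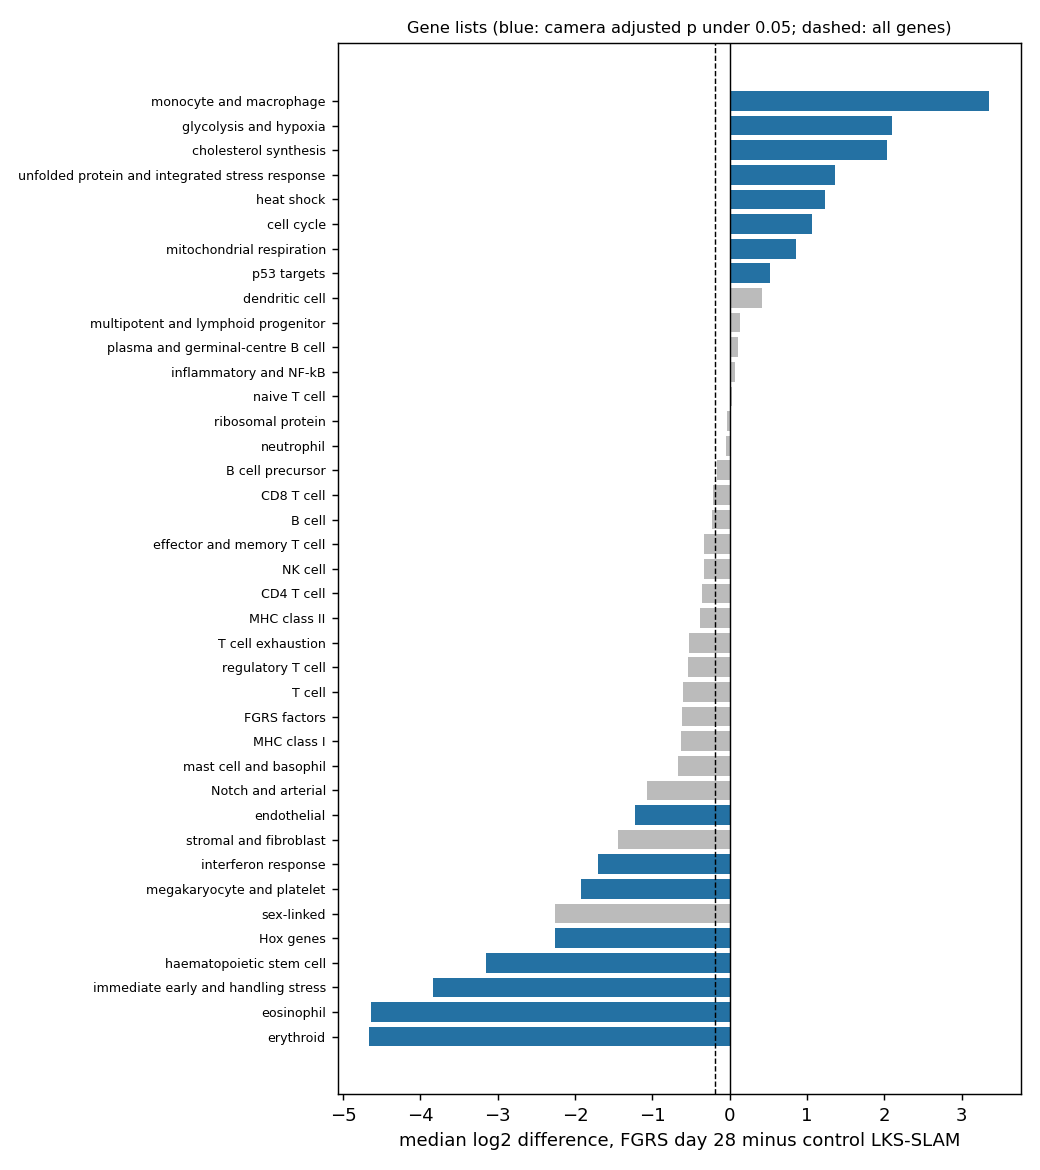
Median log2 difference, FGRS day 28 minus control LKS-SLAM, over the tested members of each of 39 gene lists; blue bars passed camera with the preset correlation and the dashed line is the median of all genes, −0.194. Cholesterol synthesis stands at 2.03, and the stem cell list at −3.15.

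The third comparison sets the cultured cells against the rEC LKS-SLAM cells recovered from marrow. Spp1 rose by 9.23 ± 0.71 (limma adjusted p = 2.53e-09) to 2217 ± 1586 from 1.65 FPKM (n = 3 each), and Lgals3 by 6.79. Granule enzymes were among the largest rises here, which they were not against controls: Ctsg rose by 7.04 to 892 ± 260 FPKM from 12.3, Mpo by 6.29 ± 0.82 to 914 ± 256 from 26.9, and Hp by 6.61. F13a1, a clotting factor subunit of monocytes, Ms4a3, a gene of granulocyte and monocyte progenitors, and the protease gene Adam8 rose by 6.21, 6.21 and 6.01. Dmkn rose by 6.29 and the inhibitory receptor gene Lilrb4a by 6.13, with reads of the latter open to sharing with its close copy. Aldh1a1, a retinaldehyde dehydrogenase, fell by 5.32 ± 0.31 (adjusted p = 4.09e-11) to 1.96 from 127 ± 65.4 FPKM, Sult1a1 by 5.68, Sdpr by 5.12, Mycn by 4.89 and the water channel Aqp1 by 4.74. The erythroid genes Car1 and Car2 fell by 5.05 and 4.92 and Hba-a1 and Hbb-b1 were listed at 0 in FGRS cells; without LKS-SLAM rEC replicate 2 and B cell rEC replicate 1 the Car1 difference was −2.33.

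Of 19 neutrophil genes 13 rose (14 adjusted over the list alone, median 3.1, camera adjusted p = 1.39e-09, and adjusted p = 0.133 with an estimated correlation), of 19 monocyte and macrophage genes 18 rose (18 rose and 1 fell adjusted over the list alone, adjusted p = 1.31e-09, and adjusted p = 0.172 with an estimated correlation), and of 36 cell cycle genes 28 rose (34 adjusted over the list alone, adjusted p = 4.99e-09, and adjusted p = 0.566 with an estimated correlation). Of 26 stem cell genes 24 fell and 1 rose (the same counts adjusted over the list alone, median −2.83, adjusted p = 2.93e-09, and adjusted p = 0.566 with an estimated correlation). Cholesterol synthesis (16 of 18 rose; 16 adjusted over the list alone, adjusted p = 3.71e-15, and adjusted p = 0.00167 with an estimated correlation), glycolysis and hypoxia (16 rose and 1 fell of 21; the same counts adjusted over the list alone, adjusted p = 3.96e-13, and adjusted p = 0.00764 with an estimated correlation) and the unfolded protein and integrated stress response (14 of 17 rose; 15 adjusted over the list alone, adjusted p = 6.02e-10, and adjusted p = 0.00047 with an estimated correlation) passed both ways. Without LKS-SLAM rEC replicate 2 and B cell rEC replicate 1 they passed with the preset correlation alone (adjusted p = 0.0569, 0.0969 and 0.0569 with an estimated correlation). Kit fell by 2.53 and Slamf1 by 3.57, and Itgam, Cd48, Spi1 and Ptprc rose by 5.17, 3.41, 2.32 and 1.03. In all 6335 genes passed, 2419 higher and 3916 lower, and in a model of these 6 libraries alone 900, 538 higher and 362 lower, where the calls of Sult1a1, Hbb-b1 and Car1 ended. Over all genes 33.3% showed no overlap, where chance gives 10%. The all-gene median was −0.137, or −0.018 after quantile normalisation.

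In blood myeloid cells, genes of surface receptors and an enzyme were among those lower in rEC, while the monocyte and macrophage list as a whole did not pass (median −0.06, camera adjusted p = 0.949). Ace, the angiotensin-converting enzyme (chromosome 11, 105967945 to 105989964), fell by 2.72 ± 0.38 (limma adjusted p = 0.000569), from 213 ± 19.1 to 32.3 ± 11.1 FPKM (n = 2 each). Cd300e, an activating receptor of monocytes, fell by 3.37 ± 0.49 (adjusted p = 0.00111), from 39.8 ± 6.66 to 4.44 ± 5.34, a call that ended without control replicate 2. The immunoglobulin-like receptor Lilra5 fell by 2.33 ± 0.22 (adjusted p = 5.01e-06), the chloride cotransporter Slc12a2 by 2.51 and the cytochrome Cyp2ab1 by 1.33. Amer2, a regulator of Wnt signalling, rose by 1.4 ± 0.18 (adjusted p = 0.00035), from 5.18 ± 0.151 to 15.7 ± 4.91 FPKM. With a pseudocount of 0.1 the calls of Ace, Cd300e, Lilra5, Cyp2ab1 and Amer2 ended and 6 genes passed, 0 higher and 6 lower (limma, 526 at an unadjusted p under 0.05 with a pseudocount of 1). In a model of the 4 myeloid libraries alone those of Cd300e, Cyp2ab1 and Amer2 ended. The make-up of the sorted myeloid cells was not measured, so these differences need not be changes within a single cell type.

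A total of 32 genes passed, 9 higher and 23 lower. The ribosomal transcript Rn45s split the groups as well, at 177 ± 26.5 FPKM in rEC and 1412 ± 22.9 in control cells, and with its level as a covariate, a setting chosen after seeing the data, 22 genes passed, 4 higher and 18 lower, each among the 32. Vcan, Ankrd66, Mmp19, Lin28a and Foxd4 rose by 1.93, 2.53, 1.3, 1.04 and 0.79, and Bcl2a1d, Ces1d, Eno3, Tef and Ip6k3 fell by 1.8, 1.78, 1.72, 1.7 and 1.21; each of these 10 calls ended without control replicate 1, without control replicate 2 and without rEC replicate 2, and that of Bcl2a1d also without rEC replicate 1. The count was 10, 9 and 15 without control replicate 1, control replicate 2 and rEC replicate 2, and 77 without rEC replicate 1. Of 21 glycolysis and hypoxia genes 0 passed in limma, also adjusted over the list alone, while the list as a whole stood higher (median 0.44, camera adjusted p = 9.65e-10, and adjusted p = 0.0452 with an estimated correlation). Of 18 cholesterol synthesis genes 0 passed (3 fell adjusted over the list alone, median −0.42, adjusted p = 9.66e-08, and adjusted p = 0.0452 with an estimated correlation). Without both libraries that stood apart in other groups these were 0.111 and 0.115 with an estimated correlation. The NK cell list (median −1.25, adjusted p = 0.00129, and adjusted p = 1.0 with an estimated correlation) and the B cell list (median −0.86, adjusted p = 0.000329, and adjusted p = 1.0 with an estimated correlation) stood lower, with 0 members passing. None of the factors and sorting markers passed. Spi1 stood at 725 ± 139 FPKM in rEC and 653 ± 31.5 in control cells, and the log2 differences were −1.31 for Fosb, −0.45 for Gfi1, 0.22 for Runx1, 0.6 for Kit, −0.11 for Ly6a, −0.05 for Slamf1, −0.57 for Cd48, −0.04 for Itgam, −0.25 for Ptprc, 0.05 for Cd3e, −0.01 for Cd4 and 0.08 for Cd8a.

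In blood B cells 0 of 14083 genes passed in limma, while 398 had an unadjusted p under 0.05. The genes with the smallest p were Trim25, an enzyme of antiviral signalling, at 42.4 ± 9.97 FPKM in rEC and 87.1 ± 10.7 in control cells (log2 difference −1.04; adjusted p = 0.0733; n = 3 each), Xlr4a at 13.6 ± 8.35 and 3.35 ± 0.630 FPKM, and Chst10 at 8.09 ± 1.91 and 17.5 ± 4.54 FPKM. The count was 5 without rEC replicate 3 and 4 without rEC replicate 2. The T cell list stood higher in rEC (median 1.95, 0 of 19 members passed, also adjusted over the list alone, camera adjusted p = 4.99e-14, and adjusted p = 0.343 with an estimated correlation). This rests on rEC replicate 1, and without it and LKS-SLAM rEC replicate 2 the median was −0.14. The B cell list stood lower (median −0.53, 0 of 18 passed; adjusted p = 3.7e-06, and adjusted p = 0.586 with an estimated correlation), which rests on the same library, since the median was 0.1 without both. None of the factors and markers passed in B cells: log2 differences were −0.74 for Fosb, 1.12 for Gfi1, 0.01 for Runx1, −0.42 for Spi1, 0.02 for Kit, −0.43 for Ly6a, 0.18 for Slamf1, 0.34 for Cd48, −0.1 for Itgam and 0.12 for Ptprc, and 2.22, 1.72 and 2.35 for Cd3e, Cd4 and Cd8a.

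In CD4 T cells 3 genes passed. Themis2, a signalling adaptor better known from B cells and macrophages (chromosome 4, 132781843 to 132796387), rose by 2.8 ± 0.34 (limma adjusted p = 0.000317), from 3.16 ± 0.193 to 29.9 ± 15.2 FPKM (n = 2 each). Pde5a, a cyclic GMP phosphodiesterase (chromosome 3, 122728947 to 122859374), fell by 2.41 ± 0.28 (adjusted p = 0.000261), from 7.8 ± 1.31 to 0.673 ± 0.458 FPKM. Speer1, which is under the expression minimum of the naming rule and is given because the count is small, rose by 0.84 ± 0.13 (adjusted p = 0.0137). The Speer1 call ended in each fit that left out a CD4 library, with a pseudocount of 0.1 and in a model of the CD4 libraries alone. Without control replicate 2 the count was 14. The sex-linked list differed (median −4.1, 0 of 5 passed over all genes, 1 rose and 4 fell adjusted over the list alone, camera adjusted p = 8.25e-07, and adjusted p = 0.0308 with an estimated correlation, or 0.324 without both libraries that stood apart in other groups). Xist, transcribed from the inactive X chromosome of female cells, stood at 74.9 ± 13.3 FPKM in rEC and 0.0569 ± 0.0466 in control cells, and the Y-linked Eif2s3y at 0.0142 and 70.9 ± 3.20. None of the factors and markers passed. Cd3e stood at 217 ± 24.6 and 283 ± 3.11 FPKM, and the log2 differences were −2.11 for Fosb, −0.12 for Gfi1, −0.04 for Runx1, 0.65 for Spi1, −0.45 for Ly6a, −0.63 for Slamf1, −0.48 for Cd48, −0.86 for Itgam, −0.39 for Ptprc, 0.04 for Kit, −0.39 for Cd4 and −1.17 for Cd8a.

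In CD8 T cells, genes of antigen-presenting cells and of the early stress response were lower in rEC than in control cells. Hspa1b and Hspa1a, inducible heat shock proteins with near-identical sequences, fell by 5.56 ± 0.6 (limma adjusted p = 1.73e-05) and 4.7, Hspa1b from 91.6 ± 95.1 to 0.414 FPKM (n = 3 each). The immediate early factors Jun and Fos fell by 4.56 ± 0.8 (adjusted p = 0.00369) and 5.02 ± 1.03, Jun from 214 ± 143 to 8.72 FPKM. Lyz2, the lysozyme of myeloid cells, fell by 5.6 ± 0.95, from 274 ± 316 to 4.99 ± 7.25 FPKM, and Fcer1g, an antibody receptor subunit, by 3.92. The class II antigen presentation genes Cd74, H2-Aa and H2-Eb1 fell by 4.25, 4.16 and 3.99, Cd74 from 714 ± 296 to 60.5 FPKM, and the linker histone Hist1h1c by 4.28 ± 0.64. The calls of Cd74, H2-Aa and H2-Eb1 ended without control replicate 1 or 2, that of H2-Eb1 also without rEC replicate 2, those of Cd74 and H2-Aa also in a model of the CD8 libraries alone, and that of Fos without control replicate 1 or 2 or rEC replicate 1 or 2.

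Themis2 rose in CD8 cells as well, by 1.86 ± 0.28 (adjusted p = 0.00128), from 16.9 ± 1.43 to 67.7 ± 26.7 FPKM. Erdr1 rose by 2.61 ± 0.47, from 212 ± 64.2 to 1263 ± 141 FPKM, Tppp by 1.49 and Xist by 5.77 ± 1.01, from 0.0428 to 62.4 ± 33.3 FPKM. The control libraries carried Y-linked transcripts, with Ddx3y at 35.8 ± 2.71 FPKM, and rEC replicate 2 carried both Xist and Ddx3y, at 28.8 and 33.8 FPKM. The rises of Exosc6, Gt(ROSA)26Sor and Ube2j2, by 1.17, 1.15 and 0.89, ended without any 1 of the 6 libraries. These calls also ended with quantile normalisation, and those of Exosc6 and Gt(ROSA)26Sor with no filter on low values. The rises of Vmn2r96 and Prss30, by 2.0 and 1.28, ended in 5 of 6 leave-outs, all but that of rEC replicate 2 and of rEC replicate 1, respectively. Both calls also ended with a pseudocount of 0.1, and that of Vmn2r96 with no filter on low values. The rise of Stk35, by 0.79, ended without control replicate 2 or rEC replicate 2.

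In CD8 cells 13 of 18 B cell genes fell (16 adjusted over the list alone, median −2.72, camera adjusted p = 4.35e-32, and adjusted p = 0.065 with an estimated correlation), among them Cd79a by 3.82 and Ms4a1 by 3.41. Of 10 class II genes 7 fell (8 adjusted over the list alone, median −2.78, adjusted p = 1.66e-19, and adjusted p = 0.0714 with an estimated correlation). Of 19 monocyte and macrophage genes 4 fell (7 adjusted over the list alone, adjusted p = 6.82e-10, and adjusted p = 0.163 with an estimated correlation), among them the growth factor receptor Csf1r by 3.5 and Cd300e by 2.24. Of 20 immediate early genes 2 fell (8 adjusted over the list alone, median −1.47, adjusted p = 6.82e-10, and adjusted p = 0.351 with an estimated correlation), and of 13 heat shock genes 2 (also adjusted over the list alone, adjusted p = 0.000209, and adjusted p = 0.351 with an estimated correlation). The T cell list did not pass (median −0.04, adjusted p = 0.984), and Spi1 and Itgam fell by 3.48 and 2.7. The other factors and markers did not pass: Fosb stood at 3.01 ± 0.471 FPKM in rEC and 41.5 ± 42.2 in control cells (log2 difference −2.91, limma adjusted p = 0.115), and the log2 differences were 0.44 for Gfi1, 0.01 for Runx1, −0.25 for Kit, −0.38 for Ly6a, −0.16 for Slamf1, −0.06 for Cd48, −0.05 for Ptprc, −0.01 for Cd3e, −0.19 for Cd4 and 0.11 for Cd8a. The calls of Cd79a and Ms4a1 ended without control replicate 1 or 2 or rEC replicate 2, and that of Cd300e without control replicate 2.

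In all 159 genes passed between the CD8 groups, 20 higher and 139 lower (49 and 127 after quantile normalisation), 8 of them unnamed models. In a model of the CD8 libraries alone 644 passed, 341 higher and 303 lower, so the balance towards falls is not kept there. Over all genes 30.6% showed no overlap, where chance gives 10%. The count was 52 without control replicate 2, 69 without control replicate 1, 69 without rEC replicate 2 and 99 without rEC replicate 3, and 453 without both libraries that stood apart in other groups.

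Over all 5 cell types, 126 genes passed in the mean origin difference, 58 higher and 68 lower (94 and 57 after quantile normalisation), and 84 had a single sign in every cell type. Of genes of antibody secretion, Jchain was lower in rEC by 2.89 ± 0.5 in this mean (limma adjusted p = 0.00555) and Mzb1 by 1.7 ± 0.29. Whether B cells or antibody-secreting cells among the sorted controls account for these falls was not tested over the 5 cell types. The falls thus need not be changes within each cell type. Hspa1b fell by 2.47 ± 0.29 (adjusted p = 0.000359), Hist1h1c by 1.96, Fos, Jun and Fosb by 2.12, 1.9 and 1.84, the B cell receptor subunit Cd79a by 1.71, the Y-linked Ddx3y by 2.38 and Cybb, a subunit of the phagocyte oxidase, by 1.34. Ddx3y was near 0 in control myeloid and B cells (0.00943 and 0.0482 FPKM), so its mean comes from the other cell types, and sex was not stated. The Hspa1b difference varied between cell types in the F test. Cd79a fell in CD8 cells, where B cells among the sorted controls may account for the fall. In B cells the fall of the B cell list rests on rEC replicate 1. Erdr1 rose by 1.48 ± 0.23, Scand1 by 1.31, Adnp by 1.05, Fam8a1 by 1.02, Ubald2 by 0.88, Sap30l by 0.81, Tmem238 by 0.8, Exosc6 by 0.79, Taf10 by 0.78 and the ubiquitin-conjugating enzyme Ube2j2 by 0.69 ± 0.1 (adjusted p = 0.00145). With the Rn45s level as a covariate, a setting chosen after seeing the data, 84 genes passed, 53 of them among the 126, and the calls of Adnp, Ubald2, Sap30l and Cd79a ended. Of the 20 named genes 13 passed in each of the 26 fits without 1 library. Fos lost its call in 18, Fosb in 6, Cd79a in 5, Tmem238 and Ddx3y in 3 each, Jun in 2 and Adnp in 1.

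In the mean difference, 3 of 10 plasma and germinal-centre B cell genes fell (4 adjusted over the list alone, camera adjusted p = 0.000144, and adjusted p = 0.0319 with an estimated correlation), as did 1 of 17 unfolded protein and integrated stress response genes (3 adjusted over the list alone, adjusted p = 0.000454, and adjusted p = 0.0396 with an estimated correlation). Without both libraries that stood apart the adjusted p with an estimated correlation was 0.128 for each. Of 18 B cell genes 2 fell (17 adjusted over the list alone, adjusted p = 3.22e-17, and adjusted p = 0.114 with an estimated correlation). The count of 126 genes was 501 without LKS-SLAM rEC replicate 2, 240 without LKS-SLAM control replicate 3 and 211 without LKS-SLAM rEC replicate 1. It was 54 and 59 without myeloid control replicates 1 and 2, 80 without myeloid rEC replicate 2, 78 without B cell control replicate 2, 75 without CD4 control replicate 1, 68 and 81 without CD4 rEC replicates 1 and 2, and 81 without CD8 control replicate 2.

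As whole profiles, libraries of different origin were on average 0.00391 farther apart, in 1 minus Pearson's r, than libraries of a single origin within a cell type, which did not pass (exact one-sided permutation p = 0.104). The difference was 0.0147 in CD8 cells, 0.0064 in myeloid cells, 0.0036 in CD4 cells, −0.0012 in B cells and −0.004 in LKS-SLAM cells. In LKS-SLAM cells the mean distance was 0.141 within rEC and 0.0388 within control. Without both libraries that stood apart the mean was 0.00966 (exact one-sided permutation p = 0.000556), but these libraries were chosen because they lay far from their own groups, so leaving them out raises the value by selection and this p is no test of origin. Without the LKS-SLAM cells, whose difference was negative, it was 0.00588 (exact one-sided permutation p = 0.00667). With any other cell type left out it did not pass, and without the CD8 cells it was 0.00122 (exact one-sided permutation p = 0.282). The CD8 controls also carried more B cell transcripts than CD8 rEC cells and differed in sex-linked ones, so the value need not reflect origin.

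The change from LKS-SLAM cells to each lineage was compared between origins across all genes. Across the 14083 genes, which are not independent replicates, the lineage minus LKS-SLAM log2 differences in rEC and in control cells had Pearson's r of 0.946 for myeloid cells, 0.926 for B cells, 0.927 for CD4 cells and 0.924 for CD8 cells. Spearman's rho was 0.941, 0.909, 0.912 and 0.909, and 91.8%, 87.8%, 87.7% and 87.4% of genes had the same sign. These values include the large differences between cell types and do not measure how alike the origins are.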

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

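The lists and the F test were planned; the tests of mixed cells, labels and depth and the counts over other splits of the libraries were chosen after the results were seen.

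The origin difference itself differed between the 5 cell types for 39 genes (limma F test), which were singled out because the difference between groups was tested directly. The genes named here were chosen after their values were seen. Retnlg had log2 differences of −6.48 in LKS-SLAM cells and 1.03 in myeloid cells (interaction adjusted p = 2.5e-05). Ace had −2.72 in myeloid, −3.22 in CD8 and 0.43 in CD4 cells (interaction adjusted p = 0.000154). The mean log2 of the monocyte and macrophage list was 2.14 to 3.32 in CD8 controls and 1.26 to 1.69 in CD8 rEC libraries. Whether monocytes among the sorted controls account for the CD8 value of Ace was not tested. Themis2 had 2.8 in CD4, 1.86 in CD8 and −0.37 in LKS-SLAM cells (interaction adjusted p = 0.000587). Hspa1b had −5.56 in CD8, −3.86 in CD4 and −0.17 in LKS-SLAM cells (interaction adjusted p = 0.00831). Among 100 splits of the libraries within cell types, 20 gave as many genes, the real one included, and the highest other gave 417, so chance is not excluded for the count. That split calls many more genes than the real one, which points to a structure of the samples other than origin. The count was 347 without LKS-SLAM rEC replicate 2, 184 without LKS-SLAM control replicate 3, 80 without LKS-SLAM rEC replicate 1, 83 without B cell rEC replicate 1, 71 without myeloid rEC replicate 1 and 25 without myeloid control replicate 2.

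The library of B220+ cells from clone 47G1 that belongs to no group carried signals above the B cell controls. The mean log2 of the erythroid list was 4.19 there and 1.92 to 3.64 in the 3 controls, and that of the neutrophil list 1.43 against 0.33 to 0.89. Its Hba-a1 stood at 562 FPKM.

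T cell transcripts stood high in B cell rEC replicate 1, where the mean log2 of the T cell list was 7.0. A wrong label on a T cell library is argued against by the B cell list, at 6.94 there and at most 5.43 in the 10 T cell libraries, and an effect of origin as such by the other rEC B cell libraries, where the T cell list reached 1.07 against 1.19 to 1.28 in controls. T cells among the sorted cells may be the source: their share, 81.4% from 18 of 19 list genes, and the B cell share, 24.9%, add to 106.4%, and abundant T cell transcripts such as Cd3e (198 FPKM), Cd8b1 (354) and Ccl5 (2750) were present. A B220 sort with a purity mask would remove most T cells, and the B220 isoform itself was not measured. RNA mixed in after sorting and a biological expression of these genes by B cells of that recipient stay open and untested.

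Stem cell transcripts stood low in LKS-SLAM rEC replicate 2, with the list at 3.09 and 25 of 26 members at their lowest of the 6 LKS-SLAM libraries. Low depth is argued against by the library of lowest depth (0.588 against 0.727), where the list stood at 5.09, and a wrong label on a culture library by the 10 genes highest in FGRS cells, whose median log2 was 0.5 there and 4.93 to 7.16 in FGRS libraries. Erythroid progenitors among the sorted cells may be the source: 8 of 11 erythroid genes other than globins were at their highest of the 6 libraries, Car1 stood at 1914 FPKM, Klf1 at 201, Gata1 at 108 and Epor at 116. Of 36 cell cycle genes 36 were at their highest too and of 5 globins 0, the whole erythroid list (5.54) lay within the controls (5.34 to 6.54), and the monocyte and macrophage list was at its highest as well (3.51 against 1.67 to 2.89), so other or mixed cells stay open. The LKS-SLAM gate requires Sca1 and CD150 and would remove such cells; Ly6a stood at 6.99 FPKM and Slamf1 at 2.46, and a trait of clone 47G1, of which this is the sole LKS-SLAM library, or of its recipient stays open and untested.

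B cell, class II and stress-response transcripts stood lower in rEC than in control CD8 cells. B cells among the sorted control cells may account for the B cell part: 16 list genes dropped by similar shares of their B cell level, 4.06 to 6.02% (highest over lowest 1.48), and a CD3 and CD8 sort would remove such cells. From the monocyte and macrophage list, 12 genes had shares of their control myeloid level from −0.17 to 12.7% (median 3.6%). No common share of monocytes describes these 12 genes. For Fos, Jun, Hspa1a and Hspa1b the B cell share and the highest monocyte share account for a median of 3.8% of the drop (59.9% for Fos, 4.4% for Jun, 3.1% for Hspa1a, 1.9% for Hspa1b), which argues against B cells and monocytes as the source for the last 3, while other cell types were not tested. A wider count was run in 2 forms. Of 139 fallen genes 116 (83.5%) had at least 50% of their drop accounted for, against 64.7% of other genes lower in rEC. With the neutrophil list included these were 96 of 139, against 53%. The shares were estimated from the same drops, and B cell list genes that set them are among the fallen genes. This count is thus no independent test. It also used a median monocyte share, although no common share describes those genes. Handling of the cells before lysis, the sex of the animals and a biological difference of rEC T cells stay open and untested.

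The counts were set against other splits of the same libraries. With 10 splits of 3 against 3 the splits are too few for a share under 0.05. LKS-SLAM rEC against control gave 186 genes in the real split, which 5 of 10 splits reached. The highest other split gave 2670, with rEC replicates 1 and 3 and control replicate 3 together, which points to a structure of the samples. The means of the eosinophil, the mast cell and basophil, and the cell cycle lists were lower in each of these libraries than in each other LKS-SLAM library. FGRS against control gave 6870 and 31 (1 of 10 splits), FGRS against rEC 6335 and 5560 (1 of 10; FGRS replicate 1 with rEC replicates 1 and 3), CD8 cells 159 and 2 (1 of 10) and B cells 0 and 0 (10 of 10; limma, 398 at an unadjusted p under 0.05). For the mean origin difference, 1 of 100 splits, the real one, reached 126 genes and the highest other gave 28. That share is under 0.05 if the libraries are independent, but it does not exclude chance. Mean Ddx3y stood at 39.6 FPKM in control and 0.00502 in rEC CD4 cells, and at 35.8 and 11.3 in CD8 cells. Sex-linked transcripts thus follow origin in CD4 cells. In CD8 cells Xist does, at 28.8 FPKM or more in rEC and at most 0.0517 in controls. Ddx3y does not, since the highest CD8 rEC library carried it at 33.8 FPKM, within the control range of 32.7 to 37.6. The splits cannot tell origin from sex. Titles shared across cell types (clone 47G1, secondary) leave open that recipients or batches are shared, and the splits do not account for that.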

How the results depend on the processing

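The settings were planned except leaving out both libraries that stood apart (B cell rEC replicate 1 and LKS-SLAM rEC replicate 2) and the Rn45s covariate, which are tests chosen after the results were seen. Where no reason is given, the cause was not tested.

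With a pseudocount of 0.1 limma called 6 genes in myeloid and 277 in CD8 cells, and the distance between origins was 0.00568 (exact permutation p = 0.0458). With no filter on low values the counts were 329 in LKS-SLAM, 93 in myeloid, 4 in B and 38 in CD4 cells, and 135 for the interaction. With a filter of 5 FPKM they were 7 in myeloid cells and 24 for the interaction, and with quantile normalisation 67 in myeloid and 1 in B cells. Array quality weights gave 6240 genes in LKS-SLAM cells, 11581 for FGRS against rEC, 368 in myeloid, 151 in B, 50 in CD4 and 1764 in CD8 cells, 2762 for the mean and 5105 for the interaction; the estimation of weights (0.023 to 27.0) stopped before converging, so these counts carry little weight. A model of the compared groups alone, with fewer residual degrees of freedom and its own spread, gave 0 in LKS-SLAM cells (186 with all groups, and 1325 at an unadjusted p under 0.05), 900 for FGRS against rEC, 1 in B, 38 in CD4 and 644 in CD8 cells. A minimum log2 difference of 1 left 3749 and 3492 genes for FGRS against control and rEC, by construction. Replicate numbers as a block gave 97 in myeloid cells, yet the numbers do not pair libraries (r = 0.075 in myeloid cells).

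Without both libraries that stood apart the counts were 1554 in LKS-SLAM, 105 in myeloid, 14 in CD4 and 453 in CD8 cells, 704 for the mean and 553 for the interaction, and the distance was 0.00966, raised by the selection of these libraries for lying far from their groups. They also add to the pooled spread. The Rn45s covariate gave 1 gene in B cells, and with both libraries left out as well 1417 in LKS-SLAM, 76 in myeloid, 39 in CD4 and 423 in CD8 cells, 297 for the mean and 604 for the interaction. With estimated correlations 15 of 312 list tests passed, against 112 with the preset correlation. Leaving out the LKS-SLAM cells gave a distance of 0.00588 (exact permutation p = 0.00667); with the other cell types left out it ranged from 0.00122 to 0.00518 and did not pass.

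Leaving out 1 library gave 101 to 1256 genes in LKS-SLAM cells, 5522 to 6743 for FGRS against control, 4671 to 8627 for FGRS against rEC, 9 to 77 in myeloid, 0 to 5 in B, 3 to 14 in CD4 and 52 to 193 in CD8 cells, 54 to 501 for the mean and 25 to 347 for the interaction. Where this leaves a group with 1 library, that library is assumed to vary like the other groups.

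The lineage correlations moved by less than the spread between libraries in each setting. Among named genes, 6711 values under planned settings stayed on their side of the threshold in the same direction, 197 newly passed and 268 no longer passed; leaving out 1 library, 6283 stayed, 57 newly passed and the rest no longer passed. Leaving out immunoglobulin and T cell receptor segments was not run, since the table lists 0 of them. Tnfrsf4 in FGRS against control reversed with quantile normalisation (0.02). Which genes depth limits was not tested.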

Other observations

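These values come from the planned lists and from genes chosen after the results were seen, and are given here without tests.

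Sex-linked transcripts differed between and within groups. Among LKS-SLAM controls, replicates 1 and 2 carried the Y-linked Ddx3y at 31.3 and 28.4 FPKM and replicate 3 carried Xist at 118, while the 3 rEC libraries carried Xist at 131, 71.0 and 157. The FGRS libraries had a mean Xist of 58.5 FPKM and Ddx3y listed at 0. In CD4 and CD8 controls Ddx3y stood at 39.6 and 35.8 FPKM. Sex was not stated for any library.

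The stromal gene Col1a1 stood at 6.66, 97.4 and 0 FPKM in LKS-SLAM controls 1, 2 and 3, and Mpo at 732, 687 and 176. The ribosomal precursor Rn45s, a transcript without a poly-A tail, stood at 177 ± 26.5 FPKM in rEC and 1412 ± 22.9 in control myeloid cells. It ranged from 136 to 5458 in CD8 rEC libraries, and group explained 0.461 of the variance of its log2 value. In rEC libraries named as secondary it stood at 460 (LKS-SLAM), 276 (B), 216 (CD4), 136 and 173 (CD8).

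The B220+ library that belongs to no group correlated most with B cell rEC replicates 3 and 2 (Pearson's r 0.9912 and 0.9911), then with the B cell controls (0.9874 to 0.9882), and with B cell rEC replicate 1 at 0.9293, the lowest of the B cell libraries. Its B cell list stood at 8.69 (controls 8.6 to 8.71) and its Cd3e was listed at 0.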
